A study of Mus musculus with 12 samples.

How the data were processed

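RNA was sequenced from inguinal white fat of mice with and without an adipocyte deletion of NDUFS4, in 12 libraries whose titles give the sex, the genotype and a replicate number from 1 to 3, which sets 4 groups of 3. Per the labels' protocols, total RNA from white and brown fat was purified with a Zymo kit and its quality checked on a Bioanalyzer. Per the submitters' processing notes, reads were counted with featureCounts and tested with limma on the mouse build GRCm39. The versions of these tools, the aligner, the gene annotation and the strand setting are not given in the sources used here.

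Each depot has a table of the authors' own comparison and a table of normalised values. The comparison tables hold, per the file headers, the columns that limma writes for a contrast: the log2 interaction, the mean log2 expression over the libraries, the moderated t-statistic, the p-value and the adjusted p-value. The log2 values are the authors' fitted coefficients, deposited as log2 fold changes, and the normalisation and offset behind them are not given in the sources used here. The t-statistic is a score the authors deposited with no fixed range. The p-values are those the authors deposited, and the deposited adjusted p-value was checked to equal the Benjamini-Hochberg adjustment over the genes of its table. The contrast is named only in the tables' names, as the KO effect in females against that in males, and the sign was read in that order. A standard error was computed as the size of the log2 interaction divided by t, and t with its p gave the same total degrees of freedom for every gene of a table, 13.4 in white fat and 33.9 in brown fat. All gene values in the text come from the authors' deposited table, while medians, list tests, intervals and differences between depots were computed from it.

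The columns of library values carry names that match no title or other label, so 48 such columns, 12 in each of the 4 tables, were used in no step. A limma fit over the 12 libraries had been planned for KO against WT within each sex and over both sexes, for females against males within each genotype, and for the overlap of calls between sexes. None of these was made, and the authors' interaction took the place of the planned fit of that contrast. Values per library, group means with their spread, library totals and depth are therefore not reported, and precision is given only as the standard error of the authors' fit. The labels list white fat libraries only, so the brown fat table is used as the authors' comparison, and its groups are not described here.

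Coordinates are those of the deposited table. They were set against GENCODE M21, which uses the older build GRCm38, where 382 of 16697 shared genes had the same start, and no position from that annotation was used. The white fat table holds 16738 genes, 16719 with a symbol, and that of brown fat 15363. Both were used without a further filter, with a threshold of 0.05 on the adjusted p.

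In all, 37 gene lists of pathways, complexes and cell types were fixed before the data were examined. A list with at least 4 measured members was tested with limma's cameraPR (limma 3.58.1, R 4.3.3) on the t-statistics with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a table. The mammary list, with 2 members in the brown fat table, was tested in white fat only. Medians of lists carry 95% intervals from 10000 bootstrap draws of their genes, which are not independent replicates. The count adjusted over the list alone repeats the Benjamini-Hochberg step on the list's own p-values. Depots were compared by the difference of both interactions over the root of their summed squared errors, with Welch-Satterthwaite degrees of freedom, which takes the tables as independent. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

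Genes were named by a rule fixed before the data were examined: Ndufs4 first, then the 10 smallest p among genes past the threshold with an informative symbol, and up to 4 members of each list with the smallest p, of which the text gives some. Genes chosen after their values were seen are marked as such. A gene that this later choice also took is not reported here. Alternatives chosen before the data were examined needed library values, except a threshold of 0.10. Those added afterwards were only genes with a mean log2 expression of at least log2 of 10, protein-coding genes only, centring on the median interaction, a minimum size of 1 on the log2 scale, and leaving out the T cell, B cell and ribosomal protein lists. For the list test they were preset correlations of 0.05 and 0.10, ranks, log2 interactions in place of t, the expression filter and centring. The parts of the naming rule for contrasts within a sex or genotype were not used.

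The steps were tested on simulated data for the white fat interaction. Over 16738 simulated genes, 22% of genes changed by 3 standard errors, 68% of those changed by 5 and 100% of those changed by 8 were called, and 5.4% of calls fell on unchanged genes. Of 50 simulated lists of 20 genes shifted up, 49 were called, as were 49 of 50 shifted down and 2 of 50 unshifted. Simulated genes were drawn independently of each other, so these rates do not cover lists whose members vary together.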

Results

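Inguinal white fat (iWAT), the subcutaneous depot of the groin, was profiled by RNA sequencing in C57BL/6 mice kept at room temperature on a high-fat diet. The study compared wild-type (WT) mice with mice whose adipocytes lack NDUFS4 (KO), an accessory subunit of respiratory complex I, the enzyme that passes electrons from NADH into the respiratory chain. Both sexes were included, which gave 12 libraries in 4 groups (WT males, KO males, WT females and KO females) of 3 libraries each. The comparison read here is the interaction of genotype and sex, taken from the authors' deposited table for white fat: the log2 KO effect in females minus the log2 KO effect in males. Another table of the same contrast, named for brown fat (BAT), was read beside it. The effect of the knockout within each sex was not analysed here, so an interaction below 0 can come from a lower value in KO females, a higher value in KO males, or differences among the WT groups. The order of the sexes is read from the table's name and is not stated in the labels, so every sign below rests on that reading. Library totals were not analysed here either, and the depth behind each value is unknown. The labels do not say how many animals a library holds, so p-values measure the spread between these libraries.

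The targeted gene was read first. Ndufs4 (ENSMUSG00000021764.9, chromosome 13, 114424331 to 114524794, GRCm39) had a log2 interaction of 0.89 ± 0.38 (standard error) in the authors' deposited table, with an adjusted p of 0.169 from limma. Its mean log2 expression over the libraries was 7.29. This difference between sexes did not pass the threshold and says nothing of how far Ndufs4 was lowered in either sex, so it does not check the genotype labels.

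Did loss of NDUFS4 change the white fat transcriptome differently in females and males? Lymphocyte genes and cytosolic ribosomal protein genes lay below 0 in the white fat interaction, while genes of the respiratory chain, the tricarboxylic acid (TCA) cycle, fatty acid oxidation and branched-chain amino acid breakdown lay above 0 as groups. Of 16738 genes in the authors' deposited table, 795 passed an adjusted p of 0.05 in limma, of which 618 (77.7%) were below 0 and 177 above. At an unadjusted p of 0.05, 4106 genes (24.5%) passed. The median interaction over all genes was 0.13, and with every gene taken relative to that shift 960 genes passed, 852 below 0 and 108 above. The smallest adjusted p was 0.0355, which many genes shared, and moving the threshold to 0.10 gave 2027 genes.

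**Figure D1:**
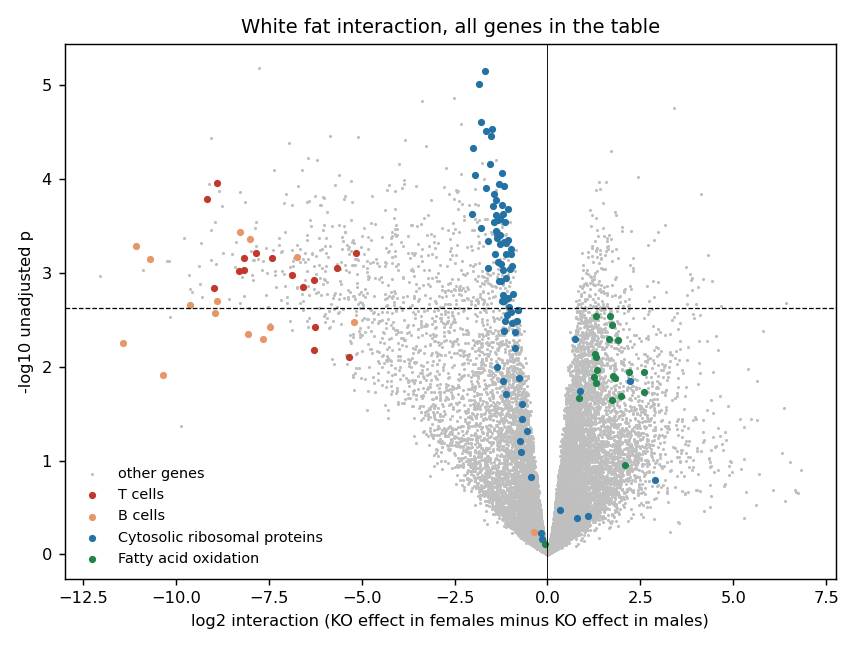
Log2 interaction (x axis, KO effect in females minus KO effect in males) against -log10 of the unadjusted p (y axis) for each of 16738 genes in the white fat table, with 4 of the fixed gene lists in colour and a dashed line at the largest p that passed an adjusted p of 0.05. Most T and B cell genes spread to the far left. Most cytosolic ribosomal protein genes form a narrow column near the list's median of -1.17, with 7 of 83 above 0. Fatty acid oxidation genes sit under the line and, except Cpt1a at -0.08, to the right.

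The T cell genes lay far below 0. All 16 measured members had a negative interaction, 13 passed the adjusted p over all genes and 16 passed when adjusted over the list alone. Their median was -7.13 (95% bootstrap interval over genes -8.17 to -6.28). Among them, the authors' deposited table gave Zap70, the kinase that relays T cell receptor signals, -8.90 ± 1.65 (standard error, adjusted p = 0.0355). Cd5, a surface receptor of T cells, was at -9.15 ± 1.77 (adjusted p = 0.0355) in the authors' deposited table. Tcf7, a transcription factor of naive T cells, was at -7.83 ± 1.76 and Cd2, an adhesion receptor, at -5.16 ± 1.16 (adjusted p = 0.0357 each) in the authors' deposited table. The B cell genes did likewise, with 15 of 15 members below 0, 7 past the adjusted p over all genes, 14 adjusted over the list alone, and a median of -8.28 (interval -10.34 to -7.46). Cxcr5, the chemokine receptor that guides B cells into follicles, was at -8.28 ± 1.75 and Blk, a B cell kinase, at -8.00 ± 1.73 (adjusted p = 0.0357 each) in the authors' deposited table. Cd22, an inhibitory receptor, was at -11.07 ± 2.44 (adjusted p = 0.0357) and Bank1, a scaffold protein, at -6.73 ± 1.54 (adjusted p = 0.0361) in the authors' deposited table. Ighm, the heavy chain of IgM and the most abundant B cell gene of the list, was the exception with -0.35 ± 0.63 (adjusted p = 0.757) in the authors' deposited table, picked out after its value was seen. As a set the T cell list (camera adjusted p = 2.25e-16) and the B cell list (5.72e-12) lay below the other genes. Mean log2 expression had a median of 1.95 over the T cell list and 2.25 over the B cell list. The size of these interactions therefore depends on how the authors' fit treats values near the floor, and is not a measured fold. Standard errors were also wide, with medians of 1.74 and 2.33. Among genes of like mean expression their median percentiles were 96.3 and 98.9. Unequal amounts of lymphocytes between libraries were thus not set apart from a KO effect.

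Messages for the proteins of the cytosolic ribosome, which translates nuclear-encoded mRNA, were lower in the interaction by a much smaller and more even amount. The list was fixed as a pattern of gene symbols, so it can also take paralogs, such as Rpl3l in brown fat. Of 83 genes, 54 passed the adjusted p below 0 and none above, and adjusted over the list alone 70 passed below 0 and 3 above. The median was -1.17 (interval -1.24 to -1.08), and the list test gave an adjusted p of 9.35e-43. Rpl23 (chromosome 11, 97668353 to 97673263) had an interaction of -1.68 ± 0.24 in the authors' deposited table, Rps18 (chromosome 17, 34170973 to 34174975) -1.85 ± 0.27, Rps7 (chromosome 12, 28680853 to 28685952) -1.80 ± 0.29 and Rpl36a (chromosome X, 133486403 to 133488811) -1.48 ± 0.24, each at an adjusted p of 0.0355. The T and B cell lists lay below 0 in the same table. Many ribosomal protein genes have processed pseudogenes, and how the authors' counting shared reads between such copies is not given in the sources used here.

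Genes of the mitochondrial respiratory chain leaned the other way. All 35 measured subunits of complex I other than Ndufs4 were above 0, with a median of 1.15 (interval 1.01 to 1.31), and the list as a set lay above the other genes (camera adjusted p = 2.05e-09). No single subunit passed, either over all genes or adjusted over the list alone. Those with the smallest p were Ndufb4, Ndufa8, Ndufa12 and Ndufb6, for which the authors' deposited table gave 1.70 ± 0.48 (adjusted p = 0.0566), 1.36 ± 0.39 (0.0611), 1.87 ± 0.55 (0.0629) and 1.32 ± 0.41 (0.0736). Of 17 assembly factors of complex I, 16 were above 0 (median 0.90, list adjusted p = 0.00390) and none passed. The 24 subunits of complexes II to IV were all above 0 (median 1.11, list adjusted p = 9.75e-08), with 11 passing adjusted over the list alone and 0 over all genes. Uqcrc1, a core protein of complex III, was at 1.91 ± 0.57 (adjusted p = 0.0660) and Cox7c of complex IV at 1.09 ± 0.36 (adjusted p = 0.0888) in the authors' deposited table. ATP synthase subunits had a median of 0.81 (13 of 15 above 0, list adjusted p = 0.0102). The 12 measured mRNAs of the mitochondrial genome were all above 0 (median 1.61, list adjusted p = 0.00176), led by mt-Nd5 with 1.79 ± 0.56 (adjusted p = 0.0726) in the authors' deposited table. Mitochondrial ribosomal proteins, which make the proteins encoded there, had a median of 0.74 with 70 of 74 above 0 (list adjusted p = 2.92e-09). None of the members of these last 3 lists passed, over all genes or adjusted over the list alone. Standard errors were wide for the expression of these genes. Ranked among genes within 0.5 log2 of the same mean expression, they had a median percentile of 92.55 for complex I and 91.6 for complexes II to IV. It was 82.6 for assembly factors, 79.3 for ATP synthase, 70.4 for mitochondrial ribosomal proteins and 67 for mitochondrial mRNAs.

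The enzymes that feed the chain also lay above 0, and a few of them passed on their own. All 20 genes of the TCA cycle and pyruvate entry were above 0 (median 1.46, interval 1.15 to 1.71, list adjusted p = 1.16e-08), with 2 past the adjusted p over all genes and 16 adjusted over the list alone. The 2 that passed over all genes were Idh3a, the catalytic subunit of NAD-dependent isocitrate dehydrogenase (chromosome 9, 54493618 to 54511945), at 2.30 ± 0.53 (adjusted p = 0.0361) in the authors' deposited table, and Mpc2. Mpc2, a subunit of the mitochondrial pyruvate carrier (chromosome 1, 165288206 to 165308783), was at 1.39 ± 0.35 (adjusted p = 0.0434) in the authors' deposited table. Relative to the median of all genes, Mpc2 no longer passed. Fatty acid oxidation had a median of 1.70 (interval 1.31 to 1.86, 19 of 20 above 0, list adjusted p = 1.48e-08), with 0 genes past the adjusted p over all genes and 18 adjusted over the list alone. Acadm, the medium-chain acyl-CoA dehydrogenase, was at 1.68 ± 0.46 (adjusted p = 0.0539) and Acadl, the long-chain enzyme, at 1.65 ± 0.49 (adjusted p = 0.0659) in the authors' deposited table. The exception was Cpt1a, which controls entry of fatty acids into mitochondria, at -0.08 ± 0.27 (adjusted p = 0.883, picked out after its value was seen) in the authors' deposited table. All 20 genes of branched-chain amino acid breakdown were above 0 (median 1.07, list adjusted p = 5.13e-08), with 2 past the adjusted p and 13 adjusted over the list alone. The 2 that passed over all genes were Pcca, a subunit of propionyl-CoA carboxylase, at 1.84 ± 0.45 (adjusted p = 0.0396) and Acat1, mitochondrial acetoacetyl-CoA thiolase, at 1.83 ± 0.45 (adjusted p = 0.0401) in the authors' deposited table. The lymphocyte lists below 0 and the skeletal muscle and thermogenic lists above 0 stood beside all of these groups in the same table. Standard errors were wide here too, with median percentiles among genes of like expression of 93.7, 94.1 and 81.75 for the 3 lists in the order given.

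Lipid-making and adipocyte genes lay above 0 as groups. The lists overlap, so their tests are not separate results in either depot. Adipocyte identity shares Cd36, Plin1, Cidec, Lpl, Lipe and Pck1 with the triglyceride list, and Slc2a4 with lipogenesis. De novo lipogenesis had a median of 1.05 (16 of 18 above 0, list adjusted p = 0.00130), and none of its genes passed over all genes or adjusted over the list alone. Acss2, which makes acetyl-CoA from acetate, was at 1.05 ± 0.31 (adjusted p = 0.0649) and Fasn, fatty acid synthase, at 1.45 ± 0.49 (adjusted p = 0.0918) in the authors' deposited table. Triglyceride synthesis and lipolysis had a median of 0.74 (19 of 21 above 0, 3 adjusted over the list alone, list adjusted p = 0.000218). Aqp7, the glycerol channel of adipocytes, was at 1.11 ± 0.32 (adjusted p = 0.0591) in the authors' deposited table. Mature adipocyte identity had a median of 0.54 (interval 0.35 to 0.88, list adjusted p = 0.00628), with 18 of 19 above 0 and none past either adjustment. Pparg, the master regulator of adipocytes, was at 1.56 ± 0.49 (adjusted p = 0.0773) in the authors' deposited table. The hormone gene Adipoq and the lipid chaperone gene Fabp4, both chosen after their values were seen, were at 0.08 ± 0.41 and 0.05 ± 0.38 in the authors' deposited table. Both lay below 0 (-0.0503 and -0.0826) once the median of all genes was subtracted. Beside these lists too stood T and B cells (medians -7.13 and -8.28), thermogenic genes (3.16) and skeletal muscle (3.29), so a change in cell mix is not set apart from a change within adipocytes.

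Thermogenic and muscle genes had large positive interactions with wide errors, and other settings of the list test ended the calls of both lists. The thermogenic adipocyte list had a median of 3.16 (interval 1.80 to 3.92, 17 of 19 above 0, list adjusted p = 0.0168), with 1 gene past the adjusted p over all genes and 2 adjusted over the list alone. That gene was Kcnk3, a potassium channel (chromosome 5, 30745514 to 30782615), at 3.20 ± 0.81 (adjusted p = 0.0438) in the authors' deposited table. Tmem26, a marker of beige adipocytes, was below 0 at -2.94 ± 1.19 (adjusted p = 0.150) in the authors' deposited table. Ucp1, the uncoupling protein of brown and beige adipocytes, was at 3.29 ± 5.70 (adjusted p = 0.749, chosen after its value was seen) in the authors' deposited table, an error larger than the estimate. Creatine and calcium cycling had 10 of 10 genes above 0 (median 1.57, list adjusted p = 0.00474) with 1 past the adjusted p and 2 adjusted over the list alone. This gene, Ckb, the brain-type creatine kinase, was at 1.53 ± 0.41 (adjusted p = 0.0496) in the authors' deposited table and no longer passed relative to the median of all genes. The creatine and calcium cycling list shares Atp2a1, at 4.96 ± 3.09 in the authors' deposited table, with the skeletal muscle list. All 16 skeletal muscle genes were above 0 (median 3.29, interval 2.56 to 3.94, list adjusted p = 0.00640), but none passed either adjustment. Myl1, a myosin light chain, was at 1.88 ± 0.56 (adjusted p = 0.0637) and Myh2, a fast myosin heavy chain, at 6.36 ± 2.57 (adjusted p = 0.150) in the authors' deposited table.

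Among stress responses, the mitochondrial chaperones and proteases were higher in the interaction, while the integrated stress response was not separated from the other genes. All 12 chaperone and protease genes were above 0 (median 1.11, list adjusted p = 0.000154), with 2 past the adjusted p and 6 adjusted over the list alone. The matrix proteases Lonp1 and Clpx were at 1.41 ± 0.31 and 1.40 ± 0.32 (adjusted p = 0.0357 each) in the authors' deposited table. The integrated stress response list, targets of the transcription factor ATF4 among them, had a median of 0.20 (15 of 25 above 0, list adjusted p = 0.223) and 1 passing gene, none adjusted over the list alone. That was Vldlr, a lipoprotein receptor, at 1.29 ± 0.34 (adjusted p = 0.0491) in the authors' deposited table, which did not pass relative to the median of all genes. The NRF2 and antioxidant list had a median of 0.58 (17 of 22 above 0, list adjusted p = 0.00523, 0 genes past the adjusted p and 5 adjusted over the list alone). Glycolysis had a median of 1.10 (14 of 16 above 0, list adjusted p = 0.000813), with 5 genes adjusted over the list alone and 1 over all genes, Aldoa, at 1.29 ± 0.31 (adjusted p = 0.0386) in the authors' deposited table. For the hypoxia response (median 0.48, list adjusted p = 0.0706) and cholesterol synthesis (median 0.53, list adjusted p = 0.127) no list difference was detected. In the hypoxia list 1 gene passed by both adjustments, Mxi1, an antagonist of Myc, at 1.44 ± 0.33 (adjusted p = 0.0361) in the authors' deposited table, and in the cholesterol list none passed by either. The chaperone, NRF2 and glycolysis calls likewise stood beside the lymphocyte lists (medians -7.13 and -8.28) and the skeletal muscle (3.29) and thermogenic lists (3.16), and are not set apart from a change in cell mix.

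Proliferation genes lay below 0, and inflammatory genes did so in part. The inflammatory list had a median of -1.41 with an interval of -1.93 to 0.34 that includes 0 (13 of 19 below 0, list adjusted p = 0.00579), with 2 genes past the adjusted p and 3 adjusted over the list alone. Ccl5, a chemokine made by T cells among others, was at -5.79 ± 1.21 and Vcam1, the adhesion receptor for lymphocytes, at -2.07 ± 0.46 (adjusted p = 0.0357 each) in the authors' deposited table. The interferon list had a median of -0.52 (15 of 21 below 0, list adjusted p = 0.0137) and no gene past either adjustment. Neutrophil genes had a median of -2.56 (6 of 7 below 0, list adjusted p = 0.0216), with 0 genes past the adjusted p and 2 adjusted over the list alone. Their median mean log2 expression was -0.19, near the floor, so this size is not a measured fold. Of 20 proliferation genes 19 were below 0 (median -1.06, list adjusted p = 0.00176). The 2 that passed, by both adjustments, were the replication licensing genes Mcm5 at -2.15 ± 0.56 (adjusted p = 0.0460) and Mcm3 at -1.94 ± 0.51 (adjusted p = 0.0482) in the authors' deposited table. Macrophage genes were not separated from the rest (median -0.22, 16 of 22 below 0, list adjusted p = 0.228, none past either adjustment), with Lyz2, lysozyme, at -1.02 ± 0.49 (adjusted p = 0.217) in the authors' deposited table. The T and B cell lists lay below 0 beside all of these groups.

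Endothelial, smooth muscle, mammary and erythroid genes lay above 0 as groups, with calls that other settings of the list test ended, and matrix and progenitor genes were not separated from the rest. Endothelial genes had a median of 0.65 (interval 0.46 to 1.14, 11 of 12 above 0, list adjusted p = 0.00433, 3 genes adjusted over the list alone). Smooth muscle and pericyte genes had one of 0.62 (10 of 10 above 0, list adjusted p = 0.0247). Mammary epithelium, which grows through this depot in females, had a median of 1.83 with 21 of 21 above 0 (list adjusted p = 0.0423). Its median mean log2 expression was 1.91, near the floor, so this size is not a measured fold. Erythroid genes had one of 0.59 with 5 of 5 above 0 (list adjusted p = 0.0437, 1 gene adjusted over the list alone). Extracellular matrix genes (median 0.49, list adjusted p = 0.0940) and adipocyte progenitor genes (median 0.22, list adjusted p = 0.671) were not called, and in neither did a gene pass by either adjustment. No gene of the endothelial, smooth muscle, mammary or erythroid lists passed over all genes. T and B cells (medians -7.13 and -8.28), skeletal muscle (3.29) and thermogenic genes (3.16) moved in the same table. A change in cell mix is therefore not set apart here either. In the Schwann cell list the myelin genes Mbp at -1.05 ± 0.24 (adjusted p = 0.0362) and Cnp at -2.37 ± 0.61 (adjusted p = 0.0446) passed below 0 in the authors' deposited table, by both adjustments. Its other 6 genes were above 0, so the list's median (0.77) and its test direction (below the other genes, adjusted p = 0.728) differ in sign. For the sex chromosome genes, Xist, the RNA that silences an X chromosome in females, was at 5.33 ± 4.10 (adjusted p = 0.438) in the authors' deposited table. The list of 5 was not called (adjusted p = 0.709). It pools Xist with 4 Y-linked genes, which a wrong sex label would move in opposite directions. Its test therefore does not check the sex labels, on which the whole contrast rests.

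Of 37 lists, 29 were called in white fat, 22 above and 7 below the other genes. These calls use a preset correlation of 0.01 between genes of a list, and a correlation estimated from library values was not analysed here. At a preset correlation of 0.10, 13 calls held: T cells, B cells, cytosolic and mitochondrial ribosomal proteins, complex I, complexes II to IV, mitochondrial mRNAs, the TCA cycle, fatty acid oxidation, triglyceride genes, branched-chain amino acid breakdown, mitochondrial chaperones and proteases, and glycolysis. The other 16 were lost there. Their adjusted p was 0.0518 for both lipogenesis and creatine and calcium cycling, 0.0568 for endothelium, 0.0636 for proliferation, and 0.0738 for complex I assembly. It was 0.0918 for both neutrophils and skeletal muscle, 0.0935 for ATP synthase, inflammatory, adipocyte identity and NRF2 genes, 0.101 for erythroid, 0.104 for smooth muscle, 0.132 for both interferon and thermogenic genes and 0.223 for mammary genes. Already at 0.05, 5 calls were lost, with adjusted p of 0.0596 for smooth muscle, 0.0606 for interferon, 0.0629 for thermogenic, 0.0644 for erythroid and 0.123 for mammary genes. With log2 interactions in place of t, 10 were lost. Their adjusted p was 0.0646 for complex I assembly, 0.0724 for mitochondrial chaperones and proteases, 0.0885 for smooth muscle, 0.105 for triglyceride genes and 0.143 for adipocyte identity. It was 0.165 for endothelium, 0.173 for both ATP synthase and interferon genes, 0.178 for NRF2 and 0.318 for erythroid genes. Among genes of higher mean expression, smooth muscle (adjusted p = 0.0952), erythroid (0.0867), interferon (0.0861) and skeletal muscle genes (0.131) were lost.

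**Figure D2:**
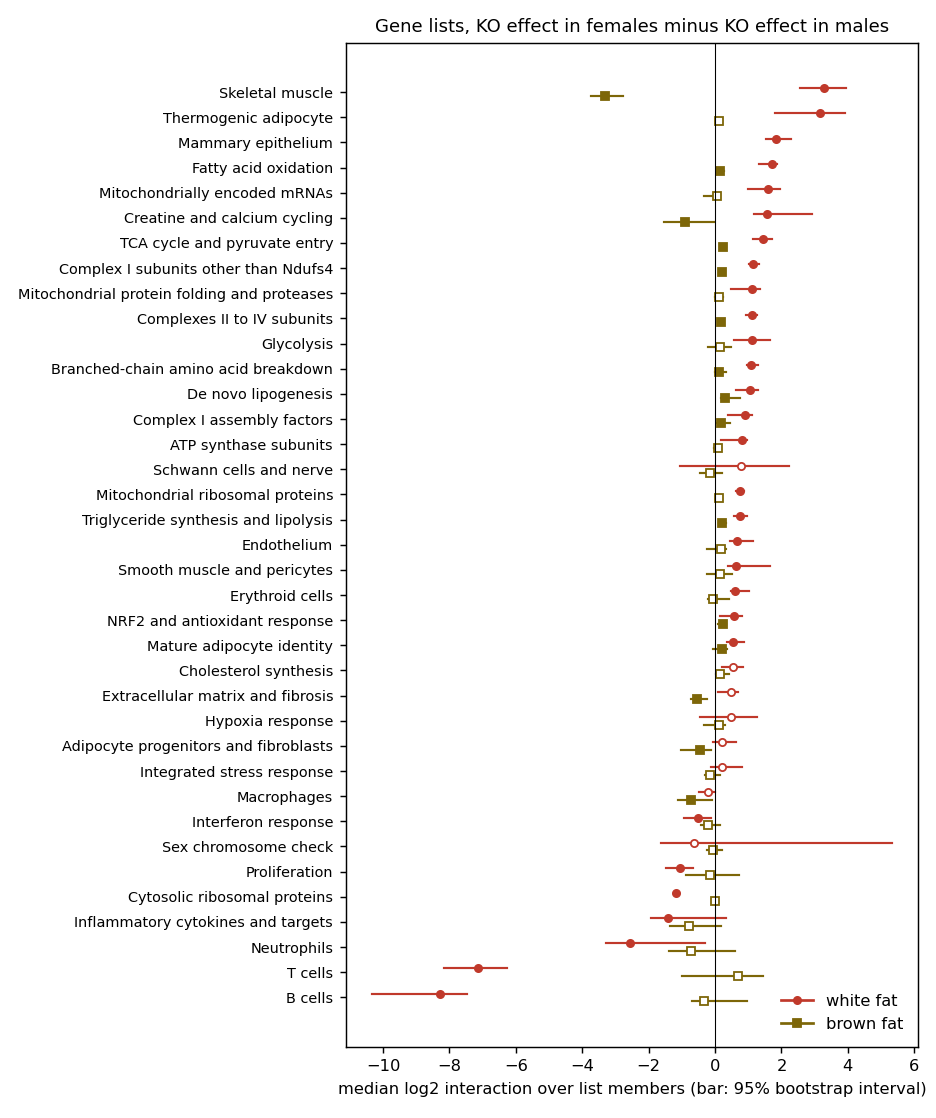
Median log2 interaction (x axis) over the measured members of each fixed gene list (y axis) in white fat (circles) and brown fat (squares), with 95% bootstrap intervals over genes and filled symbols for lists called by camera at an adjusted p of 0.05. The T and B cell medians of -7.13 and -8.28 lie far left in white fat, and skeletal muscle lies at 3.29 in white fat and at -3.30 in brown fat.

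Among the 10 genes with the smallest p and an informative symbol were the cytosolic ribosomal protein genes Rpl23, Rps18, Rps7, Rpl36a, Rpl5 and Rpl37. The others were Cbx7, a Polycomb group protein (chromosome 15, 79800008 to 79855320), at -2.51 ± 0.38 and Cdc25b, a phosphatase that starts mitosis (chromosome 2, 131028869 to 131040417), at -2.34 ± 0.37 (adjusted p = 0.0355 each) in the authors' deposited table. Scart1, a scavenger receptor known from gamma-delta T cells (chromosome 7, 139798180 to 139811058), was at -5.85 ± 0.97 and Slc46a1, the proton-coupled folate transporter (chromosome 11, 78356523 to 78362885), at 3.41 ± 0.53 in the authors' deposited table, each at an adjusted p of 0.0355. Slc46a1 was the only one of the 10 above 0. Since so few of these were above 0, some of the 10 smallest p above 0 were also read, a choice made after seeing the values. Of these, Nfe2l1, a transcription factor that drives proteasome genes, was at 1.14 ± 0.23 in the authors' deposited table. Adk, adenosine kinase, was at 1.38 ± 0.26 and Zfhx3, a homeobox transcription factor, at 1.41 ± 0.27 in the authors' deposited table. Adjusted p of these 3 genes ranged from 0.0355 to 0.0357.

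**Figure D3:**
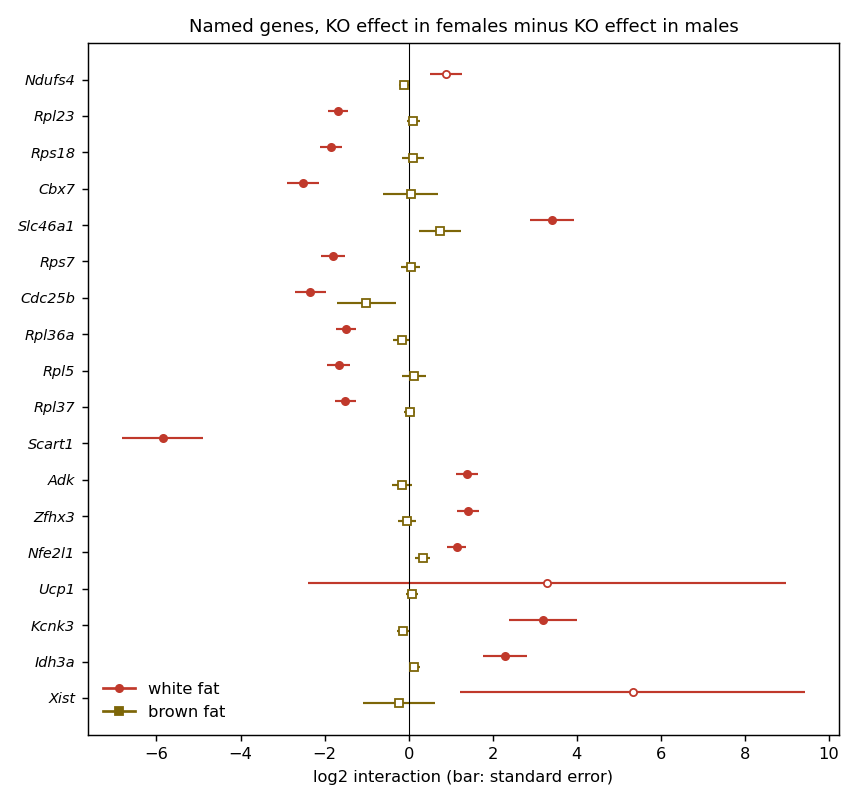
Log2 interaction (x axis) with its standard error (bars) for named genes (y axis) in white fat (circles) and brown fat (squares), filled where the adjusted p is under 0.05. Rpl23 sits at -1.68 in white fat and 0.11 in brown fat, while Ucp1 and Xist have white fat errors of 5.70 and 4.10.

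Did the same contrast look alike in brown fat? In the authors' deposited table for brown fat 2 of 15363 genes passed an adjusted p of 0.05 in limma, both above 0, and 1000 (6.5%) passed an unadjusted p of 0.05. Tmem45b, which codes for a membrane protein (chromosome 9, 31337492 to 31375758), was at 1.60 ± 0.26 (adjusted p = 0.00777) and Ntrk3, the receptor for neurotrophin 3 (chromosome 7, 77825707 to 78387760), at 1.18 ± 0.21 (adjusted p = 0.0179) in the authors' deposited table. Ndufs4 was at -0.10 ± 0.14 (adjusted p = 0.946) in the authors' deposited table. No gene of any fixed list passed, but 15 of 36 lists were called, 10 above and 5 below the other genes. Genes of the TCA cycle (median 0.24, list adjusted p = 1.46e-12), complexes II to IV (0.17, 3.10e-08), complex I (0.21, 7.24e-08) and complex I assembly (0.19, 0.0436) lay above. So did those of triglyceride metabolism (0.21, 8.27e-07), fatty acid oxidation (0.16, 1.23e-06), lipogenesis (0.29, 2.12e-05), adipocyte identity (0.21, 3.29e-05), the NRF2 response (0.25, 3.29e-05) and branched-chain amino acid breakdown (0.13, 0.000769). Of these calls complex I assembly was lost at a preset correlation of 0.05 (adjusted p = 0.139), and branched-chain amino acid breakdown at 0.10 (adjusted p = 0.0549). Skeletal muscle (median -3.30, list adjusted p = 6.15e-08), extracellular matrix (-0.55, 3.29e-05), macrophages (-0.73, 3.44e-05), progenitors (-0.45, 0.000126) and creatine and calcium cycling (-0.91, 0.0188) lay below, the last of which was lost at a preset correlation of 0.10 (adjusted p = 0.0856). The skeletal muscle genes had a median mean log2 expression of 2.08 and a median standard error of 1.67, and 0 passed adjusted over the list alone. With muscle, matrix, macrophage and progenitor lists below 0, a change in cell mix was not set apart from a change within adipocytes in brown fat either. Adjusted over the list alone, 7 TCA cycle genes passed, led by Pdha1 of pyruvate dehydrogenase at 0.36 ± 0.08 (adjusted p over all genes = 0.182) in the authors' deposited table. Likewise 3 matrix genes passed, led by Col3a1, a fibrillar collagen, at -0.81 ± 0.24 (adjusted p over all genes = 0.459) in the authors' deposited table. The other 21 lists were not called in brown fat, among them cytosolic ribosomal proteins (median -0.01, list adjusted p = 0.716), thermogenic genes (0.11, 0.296) and T cells (0.69, 0.548). For the brown fat Schwann cell list the median (-0.16) and the test direction (above) differ in sign. Lymphocyte genes were thinly covered there, with 5 of 16 T cell and 9 of 15 B cell genes in the table.

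The depots were then compared gene by gene, as the white fat interaction minus the brown fat interaction with both standard errors combined. Of 14502 shared genes, 36 differed at an adjusted p of 0.05, 23 lower and 13 higher in white fat, and 2281 differed at an unadjusted p of 0.05. Cytosolic ribosomal proteins made up 12 of the 36, and Rpl23, at -1.68 ± 0.24 in white fat and 0.11 ± 0.16 in brown fat in the authors' deposited table, differed by -1.80 ± 0.29 (adjusted p = 0.0106). Of 35 lists 22 differed at the preset correlation of 0.01. Complex I, the TCA cycle and fatty acid oxidation had median differences of 0.96, 1.16 and 1.55 (list adjusted p = 7.15e-09, 1.53e-07 and 7.13e-09). Skeletal muscle differed by 6.84 (list adjusted p = 5.82e-07), with opposite signs in the depots. Of the white fat calls, 589 were in the brown fat table, 359 with the same sign there, and 31 of them differed between depots. Across genes the interactions had a Pearson r of 0.05 and a Spearman rho of 0.09, a description only, since genes are not independent replicates. The test takes the tables as independent, although the same mice may have given both depots, and the tables were normalised separately.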

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

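Of the tests below, those on unequal lymphocyte amounts (in their present form), on oxidative genes and on Xist were chosen only after the results were seen, as were the merging of the lymphocyte and ribosomal protein patterns into 1 and the comparison of depots.

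The interaction differed between white and brown fat for 36 genes and 22 lists by the test of the difference itself. Median differences, white minus brown fat, were -8.15 for B cells, -7.98 for T cells, -1.17 for cytosolic ribosomal proteins and -1.09 for proliferation. Among metabolic lists they were 0.56 for triglyceride metabolism, 0.64 for mitochondrial ribosomal proteins, 0.74 for ATP synthase, 0.86 for mitochondrial chaperones and proteases, 0.89 for branched-chain amino acid breakdown, 0.91 for complexes II to IV and 0.96 for complex I. Glycolysis differed by 0.997, the TCA cycle by 1.16, mitochondrial mRNAs by 1.26, fatty acid oxidation by 1.55, creatine and calcium cycling by 2.52 and thermogenic genes by 3.06. The creatine and calcium cycling list shares Atp2a1 with the skeletal muscle list. That gene was at 4.96 ± 3.09 in white and -3.46 ± 1.87 in brown fat in the authors' deposited table. The creatine list's median mean log2 expression was low, 2.8 in white and 3.2 in brown fat. For cell types the median differences were 0.51 for endothelium, 0.80 for progenitors, 0.81 for erythroid cells, 0.99 for extracellular matrix and 6.84 for skeletal muscle. The T and B cell differences rest on 5 and 9 genes, with a median mean log2 expression of 0.11 in brown fat for either list. Only in the cytosolic ribosomal protein list did single genes differ, 12 of them. The list results use the preset correlation of 0.01, and no other correlation is reported here for them.

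Lymphocyte and cytosolic ribosomal protein genes lay below 0 together in white fat. A bias against short transcripts cannot be told apart for the ribosomal part. The respiratory chain genes, taken as short, had a median of 1.09 (0.95 to 1.15), which met the condition set beforehand against it. These genes belong to the oxidative pattern below, whose rise could hide such a bias, and transcript length was not analysed. A smaller share of adipocytes, moving every other cell type alike, is argued against by the endothelial median of 0.65 (0.46 to 1.14) beside the T cell median of -7.13. Unequal amounts of lymph node or blood lymphocytes cannot be told apart: the B cell median of -8.28 (-10.34 to -7.46) meets the condition set beforehand but restates the pattern, and a condition on Ighm, the most abundant member, added after its value was seen, was not met at -0.35 ± 0.63 in the authors' deposited table, while Bank1 and Ms4a1, the latter chosen after its value was seen, were at -6.73 ± 1.54 and -9.62 ± 2.55. Reads shared with pseudogenes cannot be told apart: the 73 ribosomal protein pseudogenes had a median of -0.31 (-0.61 to -0.08), a value set beforehand as speaking against sharing, but at a median mean log2 expression of 1.14 they lie near the floor, a limit recognised only afterwards. A KO effect on immune cells that differs by sex stays open and untested.

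Oxidative metabolism genes lay above 0 in white fat. Dilution of adipocyte RNA by lymphocyte RNA as the whole cause cannot be told apart. Fatty acid oxidation exceeded adipocyte identity by 1.17 (0.65 to 1.41), which met the condition set against dilution. That interval resamples genes, though, and holds no spread between libraries. Skeletal muscle in unequal amounts cannot be told apart: its mean log2 expression plus its interaction came to 6.36, with an interval (5.68 to 7.55) below 5 oxidative lists, the TCA cycle (7.62), fatty acid oxidation (7.65), mitochondrial mRNAs (7.86), ATP synthase (7.92) and complexes II to IV (8.11), but reaching past the 7.50 of complex I and the 6.50 of branched-chain amino acid genes. Thermogenic adipocytes in unequal amounts may contribute, with a list median of 3.16 (1.80 to 3.92), although its call was lost at a preset correlation of 0.05 (adjusted p = 0.0629). The condition, set after this value was seen, restates it, and the interval resamples genes and holds no spread between libraries. The list had wide standard errors, with a median of 1.70. Its most abundant genes Ebf2, Kcnk3 and Cox8b were at 1.47 ± 0.44, 3.20 ± 0.81 and 3.17 ± 1.70 in the authors' deposited table. The beige markers Tmem26 and Tnfrsf9 were at -2.94 ± 1.19 and -3.10 ± 1.37 there (Cox8b and Tnfrsf9 chosen after their values were seen). With the T cell list at a median of -7.13, lymphocytes as a source of the Tnfrsf9 value were not set apart from adipocytes. A KO effect that differs by sex stays open and untested.

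Xist had a standard error of 4.10 in white fat and 0.85 in brown fat, a ratio of 4.80 at the 99.0 percentile of 14484 genes, and the 4 Y-linked genes had a median percentile of 92.4. A library whose sex differs from the others of its group may give such errors, and this cannot be told apart from other causes. In all, 140 genes had a higher ratio, among them Fabp3 (50.3) and Ucp1 (39.6). Their white fat errors were wide (4.34 and 5.70), but their brown fat errors were small (0.086 and 0.144). Their higher ratios therefore do not speak against such a library. The measure and its bounds were set, and later made stricter, after these values were seen. No library value was used, and no biological explanation was tested.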

How the results depend on the processing

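Only the threshold of 0.10 was chosen before the data were examined, and all other tests below were chosen after the results were seen. In white fat 795 genes passed. With an adjusted p of 0.10 the count was 2027 (781 above 0, 1246 below), a looser threshold by construction. It was 551 (186 above, 365 below) among genes of higher mean expression, which held all 484 of the 484 calls tested there, 769 among protein-coding genes, 763 with a log2 size of at least 1, and 600 of 16624 genes without the T cell, B cell and ribosomal protein lists. Centring on the median of all genes gave 960 (108 above, 852 below, 88.8% below against 77.7%), with 726 of the 795 shared. Brown fat gave 2 genes in each of these. Of 29 white fat lists called, 13 held at a preset correlation of 0.10, which widens every list's error by construction, and 24 at 0.05. Among genes of higher mean expression 25 of the 29 could be tested, of which 21 held and 4 were lost, while T cells, neutrophils, mammary epithelium and creatine and calcium cycling had too few members left. With log2 interactions in place of t the count was 19, for which the cause was not tested. Ranks and centring gave 29 each. Brown fat lists ranged from 12 to 16 against 15. Directions turned, the cause was not tested, for Adipoq (-0.0503) and Fabp4 (-0.0826) on centring. They also turned for lists never called: progenitors (adjusted p = 0.936, higher expression), Schwann cells (0.809 on ranks, 0.318 on log2), the sex chromosome genes (0.631 on log2), and in brown fat B cells (0.956) and Schwann cells (0.915) on ranks. No paired analysis was possible because no library column could be given to a sample. For the same reason quantile normalisation, centring each library, pseudocounts, array weights, other priors on the spread, fits of fewer libraries, leaving out each library, count tests, an estimated correlation and other splits of the libraries were not run, and the depth behind any value is unknown.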

Other observations

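The genes below were chosen only after the results were seen, and all tests of depot differences were too. Receptor genes of lymphocytes outside the fixed lists were also below 0 in white fat. The 7 constant-region genes of T cell receptors had a median of -6.88, with 4 past the adjusted p, and the 10 constant-region genes of immunoglobulins that are in no list one of -4.76, with 2 past it. Trdc and Trgc2, constant regions of the gamma-delta T cell receptor, were at -7.37 ± 1.32 and -6.96 ± 1.17 (adjusted p = 0.0355 each) in the authors' deposited table. Glycam1, a ligand on the vessels through which lymphocytes enter lymph nodes, was at -9.87 ± 4.40 (adjusted p = 0.188) in the authors' deposited table and did not pass.

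Among the genes that differed between depots, Igkc, the kappa light chain of antibodies, had interactions of -4.31 in white and 1.49 in brown fat in the authors' deposited table, an adjusted p of 0.0106 for the difference. Satb1, a chromatin organiser of T cells, had -4.38 and 0.50 (adjusted p = 0.0443 for the difference), and Apln, the peptide hormone apelin, 1.46 and -2.64 (adjusted p = 0.0106 for the difference) in the authors' deposited table. Lmod3, which nucleates actin filaments in skeletal muscle, had 6.42 and -4.46 (adjusted p = 0.0155 for the difference) in the authors' deposited table. Its mean log2 expression in brown fat was 0.35, near the floor, so that size is not a measured fold. The skeletal muscle list also had opposite signs in the depots (medians 3.29 and -3.30), and unequal amounts of muscle were not set apart.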
